A study of Homo sapiens with 12 samples.

How the data were processed

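SHAPE-MaP was measured on 2 RNAs of PA1 cells, an established human ovarian teratocarcinoma line: the long noncoding RNA SLERT and 5S ribosomal RNA, which the labels give as a spike-in control. SHAPE-MaP reads RNA structure as mutations. NAI acylates the 2′-hydroxyl of flexible nucleotides, and reverse transcription in manganese writes a mutation into the cDNA at the adduct. Per the labels' protocols, cells received DMSO alone or NAI (200 mM, 37 °C, 10 minutes). A denatured control (DC) was heated to 95 °C in formamide; whether it then received NAI is not stated. Reverse transcription used SuperScript II with 6 mM Mn2+ and primers for each RNA, and nested PCR followed. Reads were sorted by index with bcl2fastq 2.17.1.14, per the submitters' processing notes. The aligner, the mutation counter and their versions are not given in the sources used here.

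The 12 libraries form 6 groups of 2, by RNA and condition, from the sample titles. The treatment text of all 12 samples names another condition than the title, and 1 title spells DMSO as DMSP. Each deposited table names its columns modified, untreated and denatured, and these roles set the condition of every value used here. The table for 1 RNA and 1 replicate holds all 3 conditions, and replicates were not pooled. Whether replicates came from separate cultures is not stated, so p-values measure the spread between these libraries, which may be technical.

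The deposited mutation counts, read depths and effective depths are whole-number counts per nucleotide, per the file headers. The deposited mutation rate is a fraction, and dividing mutations by effective depth gave the same values to within 4.99e-07. Per the file headers the deposited reactivity is a score, and it equalled the NAI rate minus the DMSO rate divided by the DC rate within one replicate. The authors' normalised reactivity, also a score, was that value times 1 constant per table: 7.23 and 10.4 for 5S, 1.52 and 1.33 for SLERT. Nucleotides with a DC rate of 0 or none listed had no reactivity. Those with a reactivity but no normalised value had a standard error over 0.5 or, at A148, G239 and G529 of SLERT, a DMSO mutation rate over 5%. Rates are printed here in percent.

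Median effective depth per nucleotide was 755624 and 170741 reads in the SLERT NAI libraries (replicates 1 and 2), 462245 and 117237 in DMSO and 757883 and 195922 in DC. For 5S it was 113055 and 35807 in NAI, 153052 and 97776 in DMSO and 130157 and 138093 in DC. A count of 3 mutations at the median depth is a rate of 0.0084% in the shallowest library. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. All 15 pairs of libraries of each RNA were compared, and none agreed within sampling noise. The closest pair, NAI replicates 1 and 2 of 5S, had a chi-square of 2.03 per nucleotide (p = 1.46e-07).

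Both RNAs began and ended in stretches of low mutation rate, at most 0.0516% per nucleotide in SLERT and 0.142% in 5S in any library. They were marked as running from each end to the last nucleotide before the first with a rate of at least 0.05% in all 6 libraries. This left 654 of 694 nucleotides in SLERT and 80 in 5S. The main tests kept all nucleotides with an effective depth of at least 1000 in all 6 libraries, 693 in SLERT and 120 in 5S.

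Mutation counts were tested per nucleotide with edgeR 4.0.16 (R 4.3.3), quasi-likelihood fit, with the logarithm of the effective depth as offset and no other scaling. All 6 libraries of an RNA entered 1 fit. The fit draws the spread of each nucleotide towards a spread pooled over nucleotides. In the main 5S fit the pooled spread replaced it (infinite prior degrees of freedom), so 5S p-values do not rest on each nucleotide's own replicates. Without the terminal stretches the prior degrees of freedom were 25.2. Tests were two-sided, with Benjamini-Hochberg adjustment over the nucleotides of that RNA and a threshold of 0.05. The standard errors (SE) printed for log2 changes were derived from the test, as the absolute log2 change over the square root of its F statistic. On simulated SLERT counts (654 nucleotides) the test recovered 48% of 50 nucleotides changed 1.25-fold, 94% changed 1.5-fold and 100% changed 2-fold, with 7 false calls among 454 unchanged. On simulated 5S counts (80 nucleotides) it recovered 50% of 10 changed 1.25-fold, 90% changed 1.5-fold and 100% changed 2-fold, with 0 false calls among 40. Library rates were summed mutations over summed effective depth. With 2 libraries against 2 no exact test can go below p = 0.33, so library rates were not tested.

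Profiles used the authors' normalised reactivity, each replicate apart. Medians of nucleotide classes were compared by permutation (100000 resamples), and SLERT regions by all 694 circular shifts of the region labels. Nucleotides are not independent replicates. The 5S pairs and loops were fixed from the conserved structure with 5 helices and 37 pairs. SLERT regions came from the gene table of the GRCh38.p14 assembly, used for names and lengths only: the span of SNORA5C and SNORA5A, 694 nucleotides, equals the length of the deposited sequence, and an ACA box 3 nucleotides before the end fits only with SNORA5C first. Folds used ViennaRNA 2.7.2 at 37 °C with a pseudo-energy slope of 1.8 and intercept of -0.6 kcal/mol on the normalised reactivities, negative values set to 0. Python 3.11.15, scipy 1.17.1, biopython 1.88 and matplotlib 3.10.9 were used for the rest.

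The tests, the 5S pairs and the rule for named nucleotides were set before the data were examined. For NAI against DMSO they are the 20 (SLERT) or 10 (5S) with the highest mean normalised reactivity among those called higher and positive in both replicates. For NAI against DC they are the 5 called with the largest fold change in each direction. The 5 lowest and 5 highest 51-nucleotide windows of SLERT without overlap, and every 5S helix and loop, were also named. Where fewer qualified, all were taken. Alternatives were DESeq2 1.42.0, limma 3.58.1, TMM factors, other depth and count filters, a fit of 2 groups, the replicate number as a block, each library left out, other windows and bounds, and other fold settings.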

Results

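The structure of SLERT in living cells was probed by SHAPE-MaP in PA1 cells, an ovarian teratocarcinoma line. SLERT is a nucleolar long noncoding RNA with a box H/ACA snoRNA at each end, SNORA5C at the 5′ end and SNORA5A at the 3′ end, from within the TBRG4 gene. The series concerns its role in RNA polymerase I transcription. 5S rRNA, the small RNA of the large ribosomal subunit, was probed beside it as a spike-in control. Each RNA had 2 libraries from cells treated with NAI, 2 from cells given DMSO and 2 of a denatured control (DC). Median effective depth per nucleotide ranged from 117237 to 757883 reads in the SLERT libraries and from 35807 to 153052 in the 5S libraries. Nucleotides are counted from the 5′ end of each RNA.

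The mutation rate of SLERT was higher with NAI than with DMSO, and that of 5S was not. The SLERT libraries had 0.965% ± 0.0069 (SD, n = 2) mutations per nucleotide read with NAI, 0.702% ± 0.017 with DMSO and 0.852% ± 0.014 in the denatured control. The ratio of NAI to DMSO in SLERT was 1.34 in replicate 1 and 1.40 in replicate 2. In 5S the rates were 0.239% ± 0.0062 with NAI, 0.247% ± 0.0061 with DMSO and 0.342% ± 0.0037 in the denatured control. The 5S ratio of NAI to DMSO was 1.00 in replicate 1 and 0.933 in replicate 2, and that of the denatured control to DMSO was 1.40 and 1.37. The rises in SLERT and in denatured 5S were larger than the spread between replicates. The 5S difference of NAI minus DMSO, -0.0081 percentage points ± 0.012 (SD, n = 2), was smaller than that spread. Library rates were not tested, because 2 libraries against 2 allow no exact p below 0.33.

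**Figure D1:**
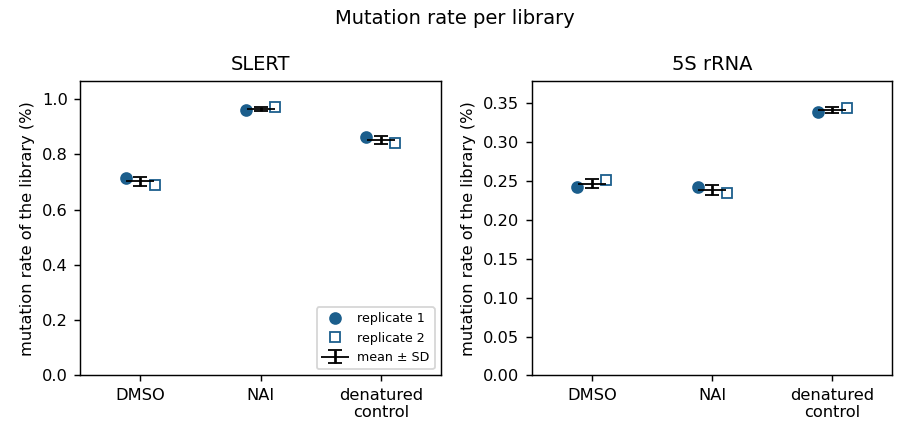
Mutation rate of each library in percent (vertical axis) by condition (horizontal axis), SLERT on the left and 5S rRNA on the right; circles are replicate 1, squares replicate 2, and bars the mean ± SD of 2 libraries. NAI lies above DMSO in SLERT (0.965% against 0.702%) and beside it in 5S (0.239% against 0.247%).

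In SLERT, 311 of 693 nucleotides had a higher mutation rate with NAI than with DMSO and 23 a lower one (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The calls spread over the whole RNA: 51 higher nucleotides lay in the SNORA5C part, 218 in the middle and 42 in the SNORA5A part. Of 656 nucleotides with a value in both replicates, 98 had a normalised reactivity over 0.85 in both and 401 one under 0.4 in both. Across nucleotides, which are not independent, normalised reactivity correlated between the replicates with Pearson's r = 0.957 and Spearman's rho = 0.842. TMM scaling, which takes the typical nucleotide as unchanged, moved the median log2 change outside the terminal stretches from 0.24 to -0.12 and the split to 167 higher and 222 lower. The count of lower nucleotides was 10 without DMSO replicate 1, 11 without DMSO replicate 2, 15 without NAI replicate 2 and 39 without NAI replicate 1.

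The 4 highest mean reactivities lay in the snoRNA ends. The 20 named nucleotides held 6 of the SNORA5C part, 7 of the middle and 7 of the SNORA5A part, and 11 of them were G. C630 in the SNORA5A part had the highest mean normalised reactivity, 11.7 ± 0.95 (SD, n = 2). Its mutation rate was 7.11% ± 0.49 with NAI, 0.288% ± 0.040 with DMSO and 0.836% ± 0.083 in the denatured control, a log2 change over DMSO of 4.60 (SE 0.10, edgeR adjusted p = 1.35e-14). G656, also in the SNORA5A part, reached 6.95% ± 0.046 against 0.329% ± 0.041 in DMSO, a log2 change of 4.42 (SE 0.083, adjusted p = 2.84e-15). G53 of the SNORA5C part had a normalised reactivity of 5.56 ± 1.38, and A100 of the same part 5.26 ± 0.54. In the middle, G522 stood highest with 5.30 ± 0.22. The others were C632, G613, G658, U674 and U576 in the SNORA5A part, G32, U117, C30 and C71 in the SNORA5C part, and G558, G402, G203, G475, G506 and C220 in the middle. The fold change over DMSO ranged from 3.41 to 24.2 over the 20, with adjusted p at most 4.82e-07, and each of the 20 was called higher in every alternative fit run for it, TMM scaling and each library left out included.

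Of the windows chosen without overlap, the 5 highest of SLERT were centred in the middle part, and 3 of the 5 lowest in the snoRNA parts. A window centred on 569, in the SNORA5A part, had medians of 0.361 and 0.350 in the 2 replicates. These lie above the named high windows at 325, 378 and 224, but the window overlaps the one at 544. The lowest 51-nucleotide window was centred on nucleotide 277, in the middle part, with a median normalised reactivity of -0.012 ± 0.013 (SD, n = 2 replicates). The next lowest were centred on 669 (-0.0044 ± 0.066, which takes in the 20 nucleotides of the 3′ terminal stretch), 82 (0.065 ± 0.018), 602 (0.098 ± 0.096) and 426 (0.104 ± 0.061). The highest was centred on 491, with 0.577 ± 0.22 and 38 of its nucleotides called higher with NAI, where the low window at 277 had 8. The other high windows were centred on 544 (0.359 ± 0.00040), 325 (0.322 ± 0.016), 378 (0.302 ± 0.062) and 224 (0.239 ± 0.021). Windows lay on the same side of the whole-RNA median in both replicates at 84.2% of 644 positions. The values depended on window length: in the longest window tried, the one at 426 rose to 0.293, above the whole-RNA medians of 0.189 and 0.210, and the one at 224 fell to 0.111.

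**Figure D2:**
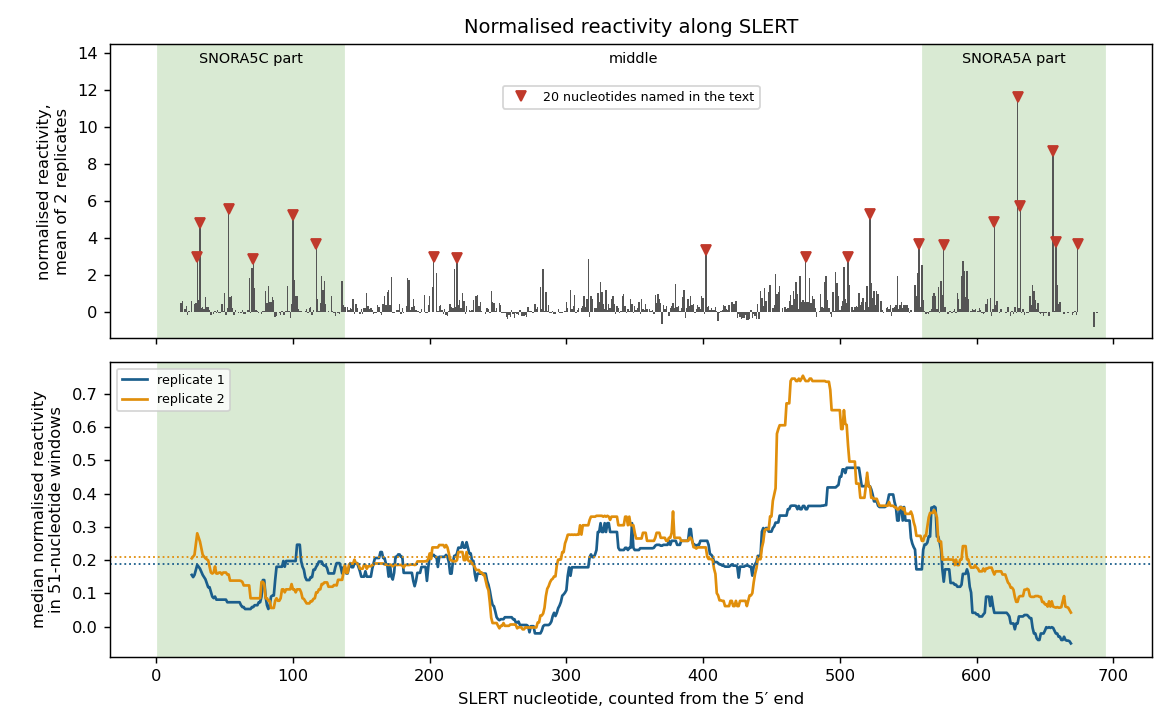
Normalised reactivity along SLERT: the upper panel gives the mean of the 2 replicates per nucleotide (triangles, the 20 named nucleotides), the lower panel the median in 51-nucleotide windows per replicate with each replicate's whole-RNA median dotted; shading marks the snoRNA parts. Both replicates fall to about 0 around nucleotide 277 and are highest around 491, where their medians are 0.418 and 0.736.

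The median reactivity of the middle part was 0.245 ± 0.021 (SD, n = 2), that of the SNORA5C part 0.138 ± 0.0055 and that of the SNORA5A part 0.0719 ± 0.059. The middle exceeded the ends by 0.141 in replicate 1 (p = 0.169, permutation by circular shifts) and by 0.132 in replicate 2 (p = 0.287), so the test did not separate them. The difference turned to -0.011 and -0.013 when SLERT was divided into 3 equal parts. By base, the mean of the replicate medians was 0.269 ± 0.050 for U, 0.258 ± 0.041 for A, 0.183 ± 0.012 for G and 0.150 ± 0.016 for C. No difference between purines and pyrimidines passed the test (two-sided permutation p = 0.848 and 0.353 in the 2 replicates).

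In the denatured control, 428 of 693 SLERT nucleotides were higher than in DMSO and 15 lower. The lower ones numbered 5 without DMSO replicate 1, 10 without DMSO replicate 2 and 6 without DC replicate 2. With TMM scaling 141 of 262 called were higher (median log2 change 0.37, and -0.011 with TMM). Between NAI and DC, 187 were higher with NAI and 217 lower, or 194 and 205 with TMM. Without DC replicate 1 the majority turned, to 157 higher and 145 lower. Among the 5 that stood out most with NAI, C630 was 8.46-fold, G656 6.42-fold and C632 4.48-fold above DC. The other 2, A8 and G682, lie in the terminal stretches: A8 had 41 mutations in NAI replicate 1 and 0 in replicate 2 against 1 in DC (ratio 44.1, exact 95% counting interval 7.48 to 1783; log2 change -2.00 without NAI replicate 1), and G682 had 63 and 15 against 5 and 1. Of the 5 lowest, C257 had 0.378% ± 0.031 with NAI, 1.16% ± 0.13 in DC and 0.671% ± 0.050 with DMSO, and so lay below DMSO too (edgeR adjusted p = 1.69e-06). U436 (0.428-fold of DC), G426 (0.438-fold) and C432 (0.440-fold) lie in the low window centred on 426. U436 (0.674-fold of DMSO, edgeR adjusted p = 0.00473) and C432 (0.624-fold, edgeR adjusted p = 0.00797) were also called below DMSO. G426 (0.863-fold of DMSO) and C18 (2.94-fold) were not called against DMSO. The remaining one, C18, is in the 5′ terminal stretch at 0.0040% ± 0.0016 with NAI and 0.0133% ± 0.0089 in DC, and was no longer called without DC replicate 1 (adjusted p = 0.193) or by DESeq2 and limma.

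Folding SLERT with its mean normalised reactivities gave 212 base pairs, with 61.1% of nucleotides paired. Folds of the single replicates paired 61.7% and 60.8% and shared 64.5% of their pairs. This is a model of minimum free energy, not a measurement. All 3 folds held 137 pairs and 15 helices of at least 5 pairs. They included 72 to 80 with 124 to 132 in the SNORA5C part, 632 to 639 with 681 to 688 in the SNORA5A part, and in the middle 156 to 165 with 288 to 297 and 457 to 467 with 529 to 539. The helix from 632 begins at the reactive C632, and its 3′ strand lies in the terminal stretch. The helix from 457 had a median normalised reactivity of 0.236, above the whole-RNA medians of 0.189 and 0.210. Those from 147, 320 and 390 also lay above both medians, and the other shared helices did not. In the mean fold, the SNORA5C part was 60.6% paired, the middle 63.6% and the SNORA5A part 53.7%. The sequence alone paired 68.01% and, by the same measure, shared 39.7% of pairs with the directed fold. A steeper pseudo-energy shared 66.03% with it and a limit on pair distance 64%, so many pairs depend on the setting.

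In 5S, 4 of 120 nucleotides were higher with NAI than with DMSO and 1 was lower, and all 4 higher ones are unpaired in the conserved structure. A83, a bulge in helix IV, had 0.560% ± 0.035 (SD, n = 2) with NAI and 0.321% ± 0.00021 with DMSO, a log2 change of 0.82 (SE 0.11, edgeR adjusted p = 3.73e-11). A88 of loop D was 1.39-fold higher (adjusted p = 0.000177), the bulged C63 1.42-fold (adjusted p = 0.0023) and C39 of loop C 1.56-fold (adjusted p = 0.0128). U96 of helix IV, named after its value was seen, was 0.782-fold (adjusted p = 0.0443). At an unadjusted p under 0.05 there were 12 nucleotides. DESeq2, limma, a minimum of 10 mutations, the fit of only the 2 groups and the replicate block each called 3 higher and 0 lower. Those 3 were among the 4 reported. TMM scaling called 4 and 0, and a single dispersion for all nucleotides only 1, A83. Without NAI replicate 2 the calls were 2, and without NAI replicate 1 or DMSO replicate 1 they were 3. A83 was called in every alternative fit, and C39 lost its call without any 1 of those 3 libraries. C63, at 0.360% and 0.478% in the NAI replicates, lost its call without NAI replicate 2 (adjusted p = 0.202) or DMSO replicate 1 (adjusted p = 0.111).

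In the denatured control, 52 of the 120 5S nucleotides were higher than in DMSO and 2 lower. TMM scaling made this 30 and 20, moving the median log2 change from 0.45 to -0.054. Among nucleotides outside the terminal stretches, calls higher in DC covered 12 of 14 in helix IV, 10 of 12 in helix III, 4 of 8 in helix II and 1 of 7 in helix V. They covered 8 of 12 in loop C, 6 of 10 in loop E, 6 of 9 in loop B, 1 of 4 in loop D and 2 of 4 bulged nucleotides. Helix I, loop A and the 3′ tail lie in the terminal stretches and could not be read. Outside those stretches, the median rise in DC was 0.0147 and 0.0174 points larger at unpaired than at paired nucleotides in replicates 1 and 2. The test, chosen after seeing the data, did not separate the classes (one-sided permutation p = 0.337 and 0.288). The median rate of helix IV was 0.466% ± 0.0090 in DC, 0.243% ± 0.012 with DMSO and 0.223% ± 0.0024 with NAI. A101 of loop E fell from 2.47% ± 0.16 with DMSO to 0.706% ± 0.015 in DC (log2 change -1.80, SE 0.071), and G66 of helix V from 2.40% ± 0.17 to 1.93% ± 0.028. Against DC, 60 nucleotides were lower with NAI and 2, A101 (3.36-fold) and G66 (1.17-fold), higher. TMM scaling made this 28 lower and 25 higher. G66 lost its call without NAI replicate 1 or DC replicate 2, and with the replicate number as a block. The 5 lowest were C19, in the terminal stretch, and C78, C34, C44 and G81, between 0.191-fold and 0.257-fold of DC.

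**Figure D3:**
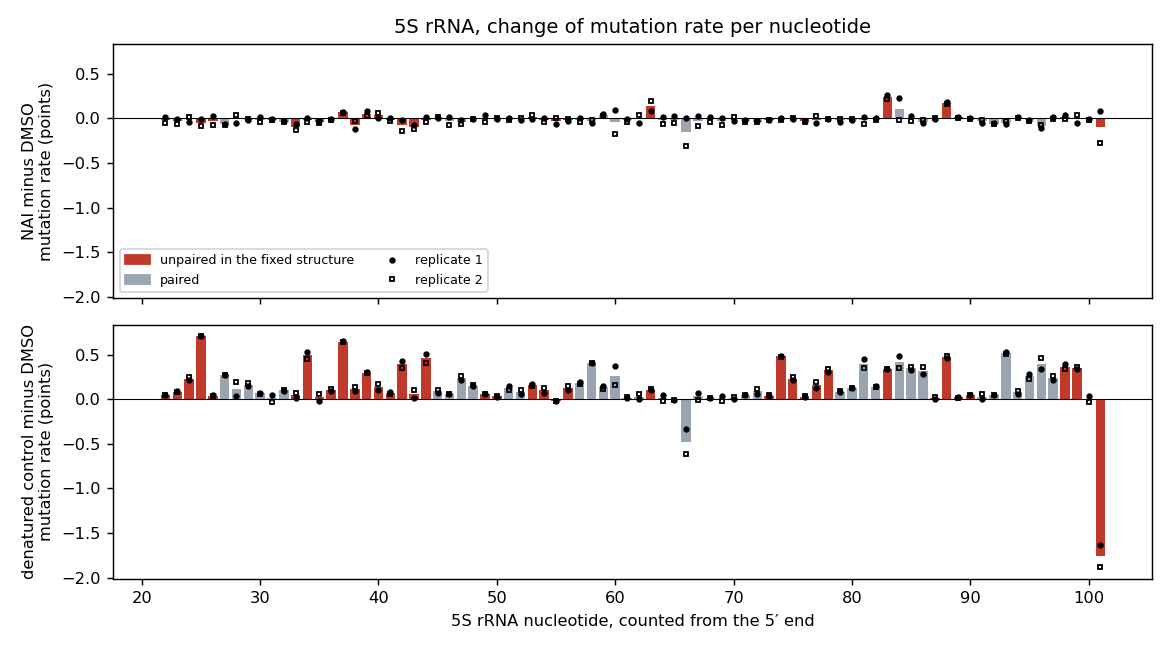
Change of the mutation rate of each 5S nucleotide against DMSO, in percentage points, with NAI (upper panel) and in the denatured control (lower panel), outside the terminal stretches; bars are the mean of 2 replicates, points the replicates, and colour marks unpaired or paired nucleotides. A83, A88 and C63 rise with NAI, C63 with a call that rests on single libraries, and A101 falls from 2.47% to 0.706% in the denatured control.

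The 5S normalised reactivities correlated weakly or not at all between replicates (Pearson's r = 0.250, Spearman's rho = -0.0038 across 84 nucleotides, and r = 0.032 without the 5 highest of each replicate). Unpaired nucleotides exceeded paired ones by a median of 0.189 in replicate 1 (one-sided permutation p = 0.110) and of 0.826 in replicate 2 (p = 0.0083), with areas under the ROC curve of 0.575 and 0.664. With the pairs of the sequence-only fold the difference was -0.020 in replicate 1 (permutation p = 0.616) and 0.874 in replicate 2 (permutation p = 0.0030). Both medians were below 0 in both replicates. Of the 9 helices, loops and bulges that could be read, loop D (0.4004 and 0.357) and the bulged nucleotides (1.12 and 1.68) had a median above 0 in both. Each of these classes holds only 4 nucleotides. Among the bulged ones, only C63 and A83, both called higher, lay above 0 in both replicates. A49 had 0.752 and -0.96, and A50 had -0.073 and 0.0065, so the bulge medians do not show a reactive class. In loop D, A88 and G89 lay above 0 in both, and G87 and A90 did not. By base, the 5S medians ranged from -0.513 ± 0.045 for U to -0.192 ± 0.24 for A (SD, n = 2). Purines exceeded pyrimidines by 0.387 in replicate 1 (permutation p = 0.0234, and 0.251 without the terminal stretches). The excess was 0.392 in replicate 2, where it did not pass the test (permutation p = 0.591). Directing the 5S fold with the mean reactivities found 83.8% of the 37 fixed pairs, where the sequence alone found 91.9%.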

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

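The Fisher test and the test of the NAI effect between the RNAs were chosen after the mutation rates had been seen, and the thinning and overdispersion tests before their results. The change with NAI differed between SLERT and 5S. The median log2 ratio of NAI to DMSO outside the terminal stretches was 0.21 in SLERT and -0.017 in 5S in replicate 1, a difference of 0.227 (two-sided permutation of the RNA over nucleotides, p = 0.00055). In replicate 2 it was 0.28 and -0.15, a difference of 0.433 (p = 1e-05, the smallest the permutations can give). The same permutation test did not separate the RNAs for the denatured control against DMSO (differences of -0.056 and -0.097, p = 0.303 and 0.0648). Nucleotides along an RNA are not independent, so these p-values are too small.

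Depth alone did not remove the SLERT calls. SLERT libraries thinned at random to the 5S depths still had a median of 46.3% of 654 nucleotides called higher with NAI. The share was at least 45.1% in each of 20 draws. The thinning kept the SLERT background, a median DMSO rate of 0.509% outside the terminal stretches against 0.251% in 5S (means of 2 libraries). It therefore covers changes of SLERT size on that background, not the changes that 5S could resolve. A lack of NAI adducts on the 5S of the NAI libraries and a low level of them cannot be told apart: the overdispersion between NAI and DMSO was 1.70 and 1.44 times that between the DMSO libraries, with overlapping bootstrap intervals, and the median change at unpaired nucleotides was -0.0020 and -0.0127 points. A mix-up of labels and a failed reaction both stay open for these libraries. A83 was called higher in every alternative fit, but these fits use the same libraries, so this 1 nucleotide does not settle the question. Of the kept nucleotides, 4 of 39 unpaired and 0 of 41 paired nucleotides were called higher, a split that missed the threshold (one-sided Fisher's exact p = 0.0520). Protection of 5S by ribosomal proteins could also lower its reactivity, but the design holds no group that tests it, so no biological explanation was tested.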

How the results depend on the processing

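The alternatives with a single dispersion or without the terminal stretches were chosen after seeing the data. So were, for mean rates, those without nucleotides over 5% in DMSO or without a replicate, and for 5S helices and loops those without a replicate. The SLERT totals of calls stayed within 1.5 times their main value in all fits except TMM for DC against DMSO (262 called). The splits moved more: TMM turned the majority for NAI against DMSO (167 higher, 222 lower), leaving out DC replicate 1 turned it for NAI against DC (157 higher, 145 lower), and with 1 library left out the lower calls ranged from 10 to 39 for NAI against DMSO (23 as reported) and from 5 to 12 for DC against DMSO (15 as reported). The 5S NAI against DMSO count, 5 as reported, was 3 with DESeq2, limma, at least 10 mutations, the fit of only the 2 groups, the z test in each replicate and the replicate block, and 1 with a single dispersion. It ranged from 2 to 6 with 1 library left out (2 without NAI replicate 2, 3 without NAI replicate 1 or DMSO replicate 1), and those fits assume that the lone library varies like the others. The cause was not tested. With the replicate number as a block, SLERT had 348, 458 and 422 calls (NAI against DMSO, DC against DMSO, NAI against DC) and 5S 3, 55 and 61. Differences between replicates correlated at 0.0047 (NAI and DMSO), -0.058 (NAI and DC) and 0.331 (DMSO and DC) in SLERT, and at 0.035, 0.232 and 0.168 in 5S. Effective depth was 97.2% to 97.3% of read depth in the 5S libraries of replicate 1 and 98.1% to 98.2% in those of replicate 2, and the labels do not say that the number marks a shared batch.

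The SLERT ratio of NAI to DMSO, 1.37, was 1.45 from median rates and 1.44 without A148, G239 and G529. The replicate correlation of SLERT was 0.931 without the 5 highest nucleotides. Undivided by DC, over all nucleotides, the 5S purine excess turned to -0.0030 points and the unpaired excess to -0.0012 points. Without the terminal stretches they were 0.0070 and 0.011 points, so the turn came with those stretches. In normalised reactivity, single replicates gave a purine excess of 0.387 to 0.392 and an unpaired excess of 0.189 to 0.826; with pairs of the sequence-only fold the latter was -0.020 and 0.874. Dividing SLERT into 3 equal parts turned its middle excess to -0.012. The paired share was 59.4% with the steeper pseudo-energy, 57.3% from pair probabilities and 68.01% without reactivities. The causes were not tested. With 1 library left out, the log2 change of A8 in NAI against DC ranged from -2.00 (without NAI replicate 1, which held all its NAI mutations) to 6.95 (without DC replicate 1). Of 68 other values for the 4 named 5S nucleotides in NAI against DMSO, 14 lost the call and none changed sign; all 320 for SLERT kept it. Of 39 other values for SLERT windows, 13 moved by more than the replicate spread, and the longest window gave no value at the 3′ end. Depth limits the 5S NAI replicate 2 library most, where 3 mutations are 0.0084%.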

Other observations

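Comparing the snoRNA ends, removing an allowed share of rate from each part, and counting shared calls were tests chosen after the data were seen. The 2 snoRNA ends of SLERT are related in sequence, with 100 of 125 aligned nucleotides identical, and their reactivity ran alike. At 86 aligned nucleotides outside the terminal stretches, normalised reactivity of the SNORA5C and SNORA5A parts correlated with Spearman's rho = 0.561 in replicate 1 and 0.619 in replicate 2 (Pearson's r = 0.362 and 0.369), above the 95th percentile of circular shifts, 0.261 and 0.251. NAI raised 36 of the 86 in the SNORA5C part and 30 in the SNORA5A part, and 22 at both, against 12.6 for independent lists and at most 20 in any shift (permutation by circular shifts, p = 0.0116, the smallest the shifts can give). G53 and its partner G613, and U117 and its partner U674, were among the 20 named nucleotides. C630 and C632 were aligned with C74 and C76, which had normalised reactivities of -0.060 and 0.210, and of -0.091 and 0.134, in the 2 replicates. The alignment has a gap just before C74 that leaves out the named C71, so these partners rest on where the gap was placed. Another gap, between U655 and U659, leaves out the named G656 and G658, so the correlations do not cover them. The pairing of A100 with U659 rests on that gap.

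Differences between the base medians do not account for this likeness: after each base's median was taken away, rho was 0.554 and 0.593, above the shifts' 95th percentile of 0.234 and 0.246. Those medians differ little, 0.150 to 0.269, and 70 of the 86 aligned nucleotides share their base. The test therefore cannot exclude an effect of base identity on the high reactivities. Reads of one part counted on the other were bounded by the DMSO mutation rate where the bases differ, a median of 0.783% and 0.756%, or 1.58 and 1.60 times that at identical bases, which lies between the bounds set beforehand. Taking that share of the partner's NAI minus DMSO rate away left rho at 0.559 and 0.567 (0.585 and 0.598 before), so cross-counting at that level does not produce it. A shared fold of the 2 snoRNA ends is a candidate explanation, and shared sequence around each nucleotide another. No group of the design separates them, and no biological explanation was tested.

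In the SLERT libraries A148 was mutated in 46.6% to 53.2% of reads and G529 in up to 49.8%, in all 6 libraries, NAI, DMSO and DC alike. G239 was mutated in 6.46% to 12.7%. The base that replaced them is not recorded in the tables used here. In 5S, log2 mutation rates of NAI and DMSO correlated at r = 0.972 and 0.966 in the 2 replicates across 80 nucleotides, beside 0.9701 between the NAI replicates and 0.979 between the DMSO replicates. In SLERT the NAI and DMSO rates correlated at 0.837 and 0.816, beside 0.985 and 0.989 within those conditions.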
